A study of Mus musculus with 7 samples.

How the data were processed

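A library of mouse DNase hypersensitive sites was assayed by capture followed by a self-transcribing reporter assay (CapStarr-seq) in P5424 cells, an immature mouse T cell line. The labels give 7 samples in 7 groups of 1 library: reporter RNA with each of 3 promoters (SCP1, the super core promoter 1; pPGK, the phosphoglycerate kinase promoter; and a promoter labelled pR-Ea), a pPGK library labelled PMA_I, and 3 inputs. The treatment field names PMA and ionomycin for every sample, so the stimulus was taken from the title of that 1 library. Only the 4 reporter libraries have processed files of their own.

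Per the submitters' processing notes, Bowtie2, SAMtools and bedtools 2.28.0 were used with build mm9; versions of the first pair, and the order of steps, are not given in the sources used here. The deposited files have no header and list reads extended to 315 bp, with a mapping quality score in column 5 and whole-number counts in columns 7 and 8. Column 7 was read as the reporter count and column 8 as the input count; no label states this. It rests on the values: column 8 was equal at every position shared by both pPGK files, with the same total of 30248710 reads, and the other 2 files have the same layout. The deposited counts belong to a 5' end position, and a position found on both strands is listed on 2 lines with the same counts, so each position was counted once. The deposited mapping quality score also showed that the authors' filters differed between files: the lowest score was 30 in the SCP1 and pR-Ea files, while 64.1% of pPGK reporter reads, 98.9% of pPGK PMA_I reporter reads and 56.0% of the pPGK file's input reads had a score of at least 30. A position was therefore used only if no file listed it below 30. That choice and the single counting were made after the files were seen and depart from counting each listed fragment, as had been planned.

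Reads were placed at the midpoint of the 315 bp fragment. Regions were built without reference to any contrast, from 7 counts (4 reporter, 3 input) thinned to 16783049 reads each and pooled: stretches of at least 200 bp in which a sliding 250 bp window held at least 3 RPM of the pool, in bins of 50 bp. A region needed at least 10 input positions in each input and at least 50% of its pPGK reporter reads at used positions, which kept 17325 of 25423 stretches. These settings were also fixed after the files were seen: 3 thresholds had been looked at together with the correlations they gave, and a share of 90% had been looked at before 50% was set. Thresholds of 2 and 5 and the share of 90% are among the alternatives. Coordinates are mm9 and start at 1. No gene names are given, because the gene table used here belongs to another build. For that reason the planned classes of tandem repeats, transcription factor sites and gene lists were not run.

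Counts were scaled to each library's reads in regions. With 1 library per group there is no replicate test and no p-value is given. A region was called higher or lower by a rule of size fixed before the data were examined: a log2 ratio of at least 1 in size (pseudocount 1), with an exact (Clopper-Pearson) 95% interval of the ratio that excludes equality, over at least 50 reads in the 2 counts. Ratios of reporter to input (called activity here) and 4 comparisons between reporter libraries were made this way. The promoter comparisons were also made on activity, the alternative named in the design; those calls need an interval over positions. The intervals cover counting error only. They are too narrow, because PCR copies are not independent molecules. The balance of strands in the SCP1 and pR-Ea files looks like that of libraries read from both ends, which was not tested; if so, 1 molecule would give 2 reads. A standard error over distinct positions (SE) is therefore given as well. It takes positions as independent, and covers their sampling and not the variation between cultures. If SCP1 and pR-Ea were read from both ends, 1 plasmid would give 2 positions. The SE of these 2 libraries, and the simulated error over positions built on it, would then be too small. A region with 0 reporter reads was given a fold at a floor of 3 counts per library, which can be larger than the bound of its counting interval.

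The rule was tested on simulated counts for the 17325 regions with 200 regions changed. In the pPGK PMA_I comparison, with error over positions, it recovered 96 of 100 regions changed by 1.5 on the log2 scale and 100 of 100 changed by 2, and called 18 unchanged regions. For pPGK against SCP1, pR-Ea against SCP1 and pR-Ea against pPGK it recovered 86, 87 and 83 of 100 at 1.5 and 98 of 100 at 2 in each, and called 1313, 634 and 1133 unchanged regions. With counting error alone it called at most 1 unchanged region in any comparison. The counting interval held the simulated value in 95.2% to 95.6% of regions with counting error alone. With error over positions that share was 56.2% for pPGK PMA_I against pPGK, 23.1% for pPGK against SCP1, 29.6% for pR-Ea against SCP1 and 24.6% for pR-Ea against pPGK.

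Regions named are those whose interval bound nearest to 0 lies farthest from 0, up to 12 on each side, of which the leading ones are printed in order of rank; any other region is said to be chosen after its values were seen. Alternatives planned were distinct positions, count minimums of 20, 200 or none, a median log2 ratio of 0, TMM scaling, a pseudocount of 5, windows of 500 bp, thinning, autosomes only, a 1.5-fold threshold, and leaving out the 0.1% most abundant regions. Counting distinct positions takes each position once whatever its reads, so it understates ratios where positions were read many times. Alternatives added after the data were seen are named with their results in the closing section. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9.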

Results

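Reporter activity of DNase hypersensitive sites was measured in P5424 cells, an immature mouse T cell line, with 3 promoters and, for pPGK, in a library labelled PMA_I, for PMA and ionomycin. PMA is a phorbol ester that activates protein kinase C and ionomycin is a calcium ionophore, and together they mimic signalling from the T cell receptor. In this assay each fragment sits in the transcript it regulates, so its reads in RNA over its reads in the plasmid input measure its output relative to the other fragments. Each group held 1 library, so no value below has a replicate check, and differences are between these libraries rather than between conditions. The files held 54992717 reporter and 45278192 input reads for SCP1, 72217277 and 30248710 for pPGK, 61707100 reporter reads for pPGK PMA_I with the same input, and 51450446 and 18940646 for pR-Ea. The 17325 regions had a median length of 450 bp, and the median region held 935 reporter reads with SCP1, 716 with pPGK, 818 with pPGK PMA_I and 758 with pR-Ea.

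The series title concerns silencers in T cells, and the ratio to input ranks sites by reporter output. Both counts were scaled to their totals over these regions, so the ratio is relative to the average of the sites. No neutral insert served as a baseline. A region below input is therefore not shown to silence, nor a region above it to enhance. Regions below input outnumbered those above it with SCP1, pPGK and pR-Ea. With SCP1, 2166 of 17304 regions were at least 2-fold below input and 566 above. The counts were 1359 below and 586 above of 17323 with pPGK, and 1212 below and 117 above of 17319 with pR-Ea. In pPGK PMA_I the 2 sides were close, at 1308 below and 1235 above of 17324. The median log2 ratio was -0.13 with SCP1, 0.09 with pPGK and 0.08 in pPGK PMA_I. Scaling to a median ratio of 0 subtracted these medians, which raised the SCP1 ratios and lowered those of both pPGK libraries. The splits then were 1730 below and 827 above with SCP1, 1579 and 378 with pPGK, and 1530 and 955 in pPGK PMA_I. Counting distinct positions in place of reads called 607 below and 53 above with SCP1, 200 and 112 with pPGK, 125 and 116 in pPGK PMA_I, and 165 and 9 with pR-Ea. Of those above, 44, 48, 83 and 3 had been called above by reads, and of those below 571, 195, 122 and 163 had been called below. A count of positions saturates in regions with many reads and not in those with few. Its split of the 2 sides therefore does not show which side is sounder. The order of the 2 sides was not fixed in the pPGK libraries. In pPGK PMA_I it reversed to 1783 above and 1220 below without a mapping quality filter, 932 and 733 in regions with 90% of pPGK reads at used positions, and 3856 and 2915 at a 1.5-fold threshold, where pPGK also had 2934 above and 2807 below.

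**Figure D1:**
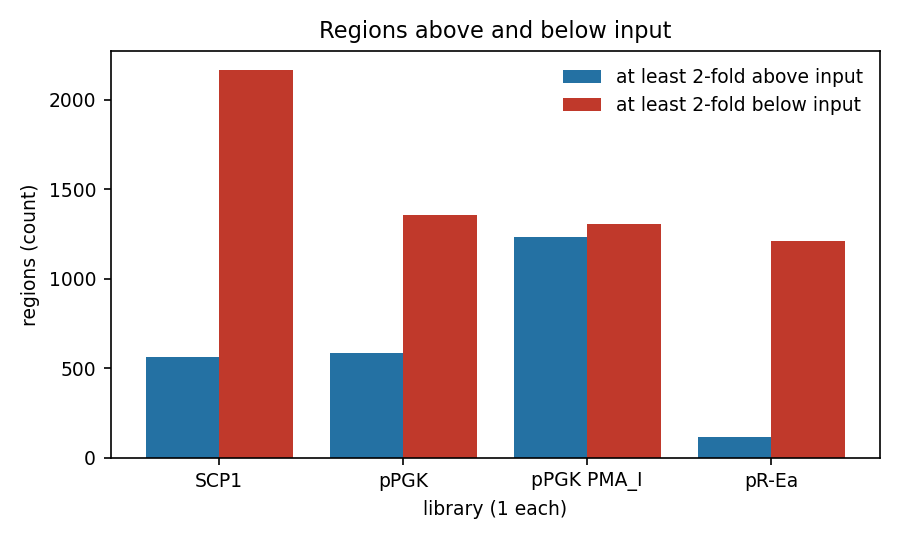
Number of regions (vertical axis, count) at least 2-fold above input (blue) or below input (red) in each of the 4 reporter libraries (horizontal axis, 1 library each). Regions below input outnumber those above with SCP1 (2166 and 566), pPGK (1359 and 586) and pR-Ea (1212 and 117), and are close in pPGK PMA_I (1308 and 1235).

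The highest SCP1 activity by the naming rule was at chromosome 11, 23913601 to 23914300, with 133613 reporter and 9481 input reads, a log2 ratio of 3.47 (SE 0.05 over positions). The same region had a log2 ratio of 2.17 (SE 0.05) with pPGK. Chromosome 19, 43786051 to 43786550, followed with 3.42 (SE 0.48), and chromosome 12, 70855601 to 70856000, with 3.36 (SE 0.27). With pPGK the leading region was chromosome 7, 149853351 to 149854250, at 2.51 (SE 0.08), which had 3.17 (SE 0.10) with SCP1 and 1.13 (SE 0.04) with pR-Ea. In pR-Ea the leading regions were chromosome 10, 24740951 to 24741350, 5.66-fold above input (log2 SE 0.19), with 2963 reporter and 190 input reads, and chromosome 5, 147804251 to 147804700, at a log2 ratio of 2.15 (SE 0.18). In pPGK PMA_I, chromosome 11, 43313001 to 43313300, led with 2.95 (SE 0.21). By distinct positions the SCP1 values were 0.47, 0.93 and 1.40 in the order given, of which the last kept its call. The others were 0.39 for the pPGK leader, 0.67 and 0.35 in pR-Ea, all without a call, and 1.09 in pPGK PMA_I, still called. The leading SCP1 region held its reporter reads on 529 positions and its input reads on 419, so this count could hardly show its ratio of reads. With an interval over positions the SCP1 regions named above input and the pPGK leader kept their calls.

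At the other end, the region at chromosome 7, 125828951 to 125829250, gave 0 SCP1 reporter reads against 488 input reads. That is 207-fold below input at the floor of 3 counts, with a 95% interval of the log2 ratio that reaches up to -7.39. Chromosome 1, 136620951 to 136621350, gave 1 against 450, a log2 ratio of -8.17 (95% interval -14.47 to -6.68). Chromosome 18, 74799651 to 74799850, gave 0 against 275, 117-fold below at the floor (interval up to -6.56). With pPGK, chromosome 11, 3968651 to 3969050, held 7 reporter reads against 872 input reads, a log2 ratio of -8.04 (SE 0.72). In pR-Ea the lowest was chromosome 3, 32781901 to 32782150, with 7 against 186 reads and a log2 ratio of -6.00 (SE 0.71). That region also had 3 reporter reads with SCP1 and 1 with pPGK. By distinct positions all 5 low regions stayed below input, at -6.08 for the SCP1 region with 1 read, -3.96 with pPGK and -4.09 with pR-Ea. The SCP1 regions with 0 reads were at -6.97 and -6.34, values set by the pseudocount. Few reporter reads leave few positions, so these regions could hardly have turned out otherwise. With an interval over positions, the SCP1 regions with 0 reads had no SE and lost their calls. The SCP1 region with 1 read kept its call.

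Of the 17296 regions tested with all 3 promoters, 564 were below input with each, where independent lists would share 11.8, and 2 were above input with each, where they would share 0.129. Their median log2 ratios were -2.11 with SCP1, -2.02 with pPGK and -1.70 with pR-Ea. Chromosome 2, 105249551 to 105249900, led these regions, named after their values were seen, with log2 ratios of -5.72 (SE 0.70), -6.25 (SE 0.41) and -4.08 (SE 0.28). Chromosome 1, 43193151 to 43193950, rested on more reads, 1513 of SCP1 reporter and 16637 of its input, with log2 ratios of -3.81 (SE 0.11), -3.52 (SE 0.10) and -3.04 (SE 0.08). In the same 564 regions the median share of pPGK reporter reads at excluded, low mapping quality positions was 15.0%, against 2.10% in the others. The 2 regions above input with all 3 promoters were the one on chromosome 7 given above and chromosome 12, 82961051 to 82961400, at 1.94 (SE 0.14), 1.45 (SE 0.18) and 1.10 (SE 0.12). For pairs of promoters, 995 regions were low with SCP1 and pPGK (170 for independent lists), 733 with SCP1 and pR-Ea (151) and 635 with pPGK and pR-Ea (95.1). On the high side 188 regions were shared by SCP1 and pPGK (19.1), 9 by SCP1 and pR-Ea (3.83) and 8 by pPGK and pR-Ea (3.95). Across regions, which are not independent replicates, activity had a Spearman rho of 0.63 between SCP1 and pPGK, 0.42 between SCP1 and pR-Ea, and 0.48 between pPGK and pR-Ea.

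**Figure D2:**
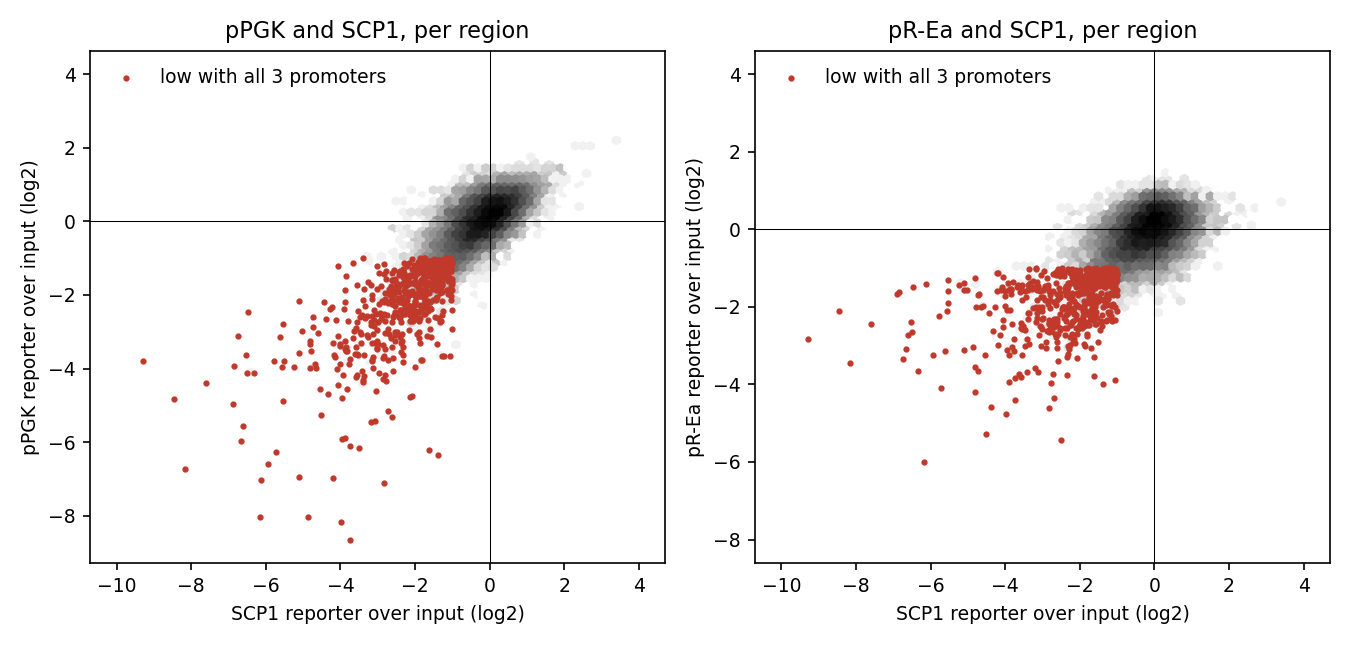
Log2 ratio of reporter to input reads per region with SCP1 (horizontal axes) and with pPGK or pR-Ea (vertical axes), 1 library each; grey cells are darker where more regions fall, on a log scale. Red points are the 564 regions chosen for being at least 2-fold below input with all 3 promoters, with medians of -2.11, -2.02 and -1.70.

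The comparison of pPGK PMA_I with pPGK addresses how the stimulus changed output from 1 promoter. By the rule of size 90 regions were higher and 9 lower of 17301. The balance of the 2 sides varied with the settings: 79 were higher and 42 lower without the position with most reads, 76 and 24 in 500 bp windows, 108 and 24 without a mapping quality filter, 78 and 15 with the median set to 0, and 56 and 1 in regions with 90% of pPGK reads at used positions. The largest rise by the naming rule was at chromosome 9, 118980001 to 118980250, from 33 to 202 reads, a log2 ratio of 2.45 (95% interval 1.95 to 3.07, SE 0.24 over positions). Chromosome 16, 94941201 to 94941700, went from 2284 to 7093 reads (log2 1.51, SE 0.14) and its activity from 0.76 to 2.27. Chromosome 4, 152268101 to 152268500, followed with 1.59 (SE 0.11), chromosome 8, 48626601 to 48626950, with 1.69 (SE 0.24), and chromosome 11, 69092751 to 69093150, with 1.64 (SE 0.23). The next were chromosome 8, 12546851 to 12547150, at 1.76 (SE 0.42) but -0.05 on the plus strand alone, chromosome 11, 99955501 to 99955750, at 1.63 (SE 0.56), and chromosome 19, 6493751 to 6494150, at 1.49 (SE 0.14). Counted by distinct positions these 8 regions ranged from 0.47 to 0.94. The regions called lower were led by chromosome 17, 35759751 to 35759950, from 253 to 54 reads (log2 -2.33, SE 0.56), and chromosome 10, 19458151 to 19458400, from 316 to 99 (log2 -1.79, SE 0.55), which were at -0.44 and -0.25 by distinct positions. Chromosome 9, 71530101 to 71530350, at -1.70 (SE 0.59), was at 0.18 by distinct positions.

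Most regions called higher had low activity without the stimulus. Of the 90, 67 were below input with pPGK, whose reads enter the comparison, and 64 with SCP1 and 53 with pR-Ea, whose reads do not. Of all regions, 2166 of 17304 were below input with SCP1 and 1212 of 17319 with pR-Ea. The 90 regions had a median log2 activity of -2.45 with pPGK and -1.10 in pPGK PMA_I, where 51 of them were below input. These calls rest on read numbers: with distinct positions in place of reads 4 regions were higher and 7 lower, and 1 of the 99 main calls was kept. A count of positions can hardly follow a change in reads per position, so this loss does not decide whether the calls are sound. The region on chromosome 16 that went from 2284 to 7093 reads went from 71 to 83 reporter positions. With an interval over positions, 95 of the 99 calls were kept. Simulated unchanged regions with error over positions gave 18 calls. Activity with pPGK also differed between the strands of a region, with a Spearman rho of 0.18 between strands over 14452 regions and 0.73 between random sets of positions over 16072 regions, and pPGK PMA_I had 0.47 and 0.80. The change itself had a rho of 0.09 between strands and 0.41 between random sets of positions.

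**Figure D3:**
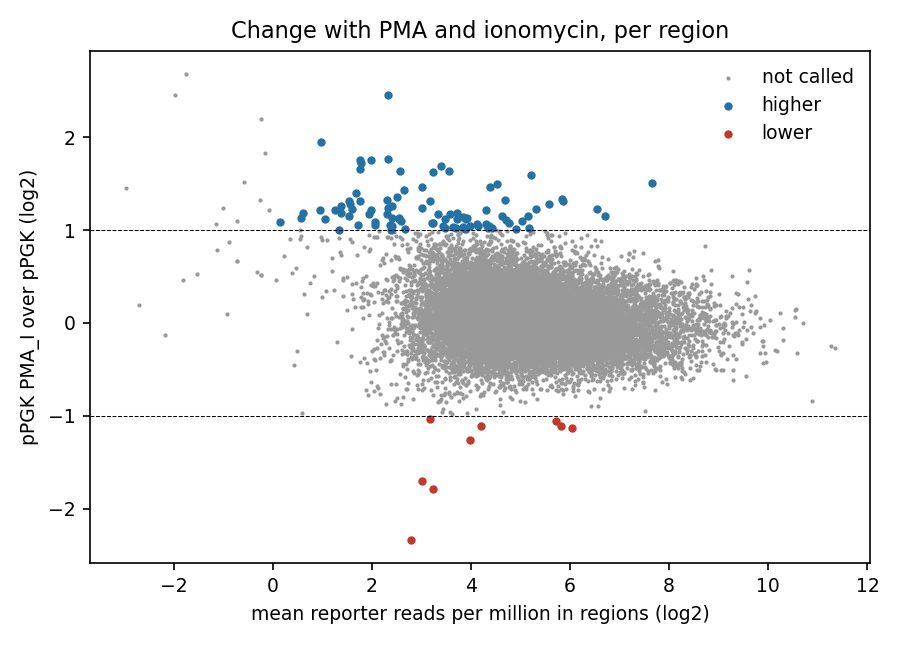
Log2 ratio of pPGK PMA_I to pPGK reporter reads (vertical axis) against mean reporter RPM in regions on a log2 scale (horizontal axis), 1 point per region and 1 library per group. Blue points are the 90 regions called higher and red points the 9 called lower; dashed lines mark 2-fold.

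**Figure D4:**
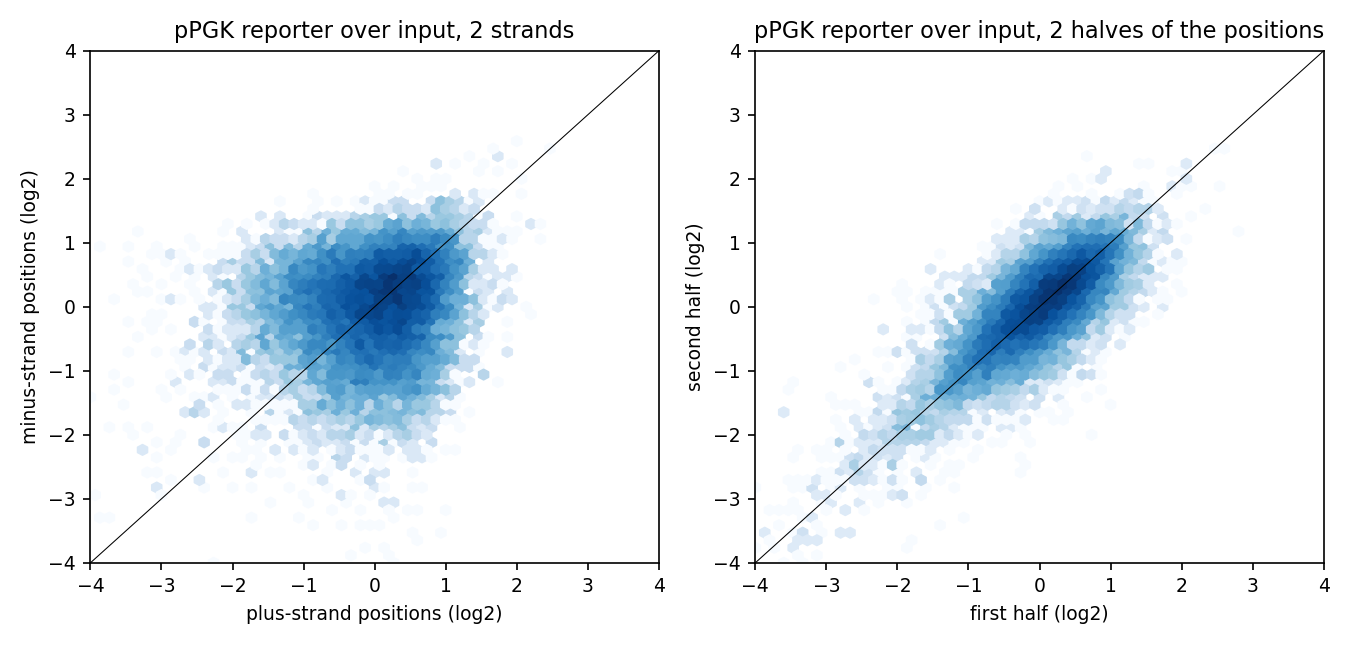
Log2 ratio of pPGK reporter to input reads per region, from plus-strand (horizontal) and minus-strand (vertical) positions in the left panel and from 2 random sets of positions in the right panel, in 1 library; darker cells hold more regions and the line marks equality. Spearman rho was 0.18 between strands and 0.73 between random sets.

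Promoters were compared first on reporter reads alone, as fixed before the data were examined. With pPGK, 5286 regions were higher and 2282 lower than with SCP1, of 17286. With pR-Ea, 3536 were higher and 2212 lower than with SCP1, of 17308, and 1816 higher and 3566 lower than with pPGK, of 17317. Counting distinct positions gave 2213 higher and 1761 lower, 1041 and 590, and 879 and 1224 in these comparisons, and kept 42.8%, 25.6% and 28.2% of the calls. The plasmid inputs differed between promoters too, and the ratio of reporter reads had a Spearman rho of 0.90, 0.76 and 0.78 across regions with the ratio of input reads in these 3 comparisons; regions are not independent replicates. Divided by input, the counts were 1185 higher and 250 lower for pPGK against SCP1, 1319 and 874 for pR-Ea against SCP1, and 690 and 1019 for pR-Ea against pPGK. The share of reporter-only calls also made after division was 13.7%, 25.9% and 20.8%, and 52, 26 and 30 were called on the opposite side. The median log2 ratio of reporter reads was 0.18, 0.14 and -0.17. With that median set to 0 the reporter-only split was 2937 higher and 2765 lower for pR-Ea against SCP1, and 2480 and 2802 for pR-Ea against pPGK (2367 and 2881 with TMM scaling).

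For pPGK against SCP1, the region at chromosome 4, 38932651 to 38932900, held 456 and 1 reporter reads, a log2 ratio of 8.37 (95% interval 6.88 to 14.67) that was 4.47 (SE 1.45) after division by input. Chromosome 11, 91054451 to 91054700, held 538 and 3 reads, at 7.60 (95% interval 6.46 to 10.30) and 3.77 (SE 0.97). Chromosome 1, 95612001 to 95612400, held 2957 and 40, at 6.70 (SE 0.59) and 1.13 (SE 0.70). On the lower side, chromosome 4, 155177351 to 155177800, was at -3.69 (SE 0.67) and -1.33 (SE 0.37), and chromosome 15, 98702301 to 98702850, at -3.44 (SE 0.59) and -0.66 (SE 0.29). Chromosome 9, 22272551 to 22272950, was at -3.37 (SE 0.65) and 0.06 (SE 0.28). The leading region lower with pR-Ea than with SCP1 by reporter reads was chromosome 14, 54847101 to 54847550 (-4.23, SE 0.42), at -3.50 (SE 0.27) by activity. By activity the first was chromosome 4, 155153351 to 155153750, at -3.82 (SE 0.30). Second by reporter reads was chromosome 17, 87601651 to 87602150, at -4.09 (SE 0.45), and -2.84 (SE 0.30) by activity. Chromosome 11, 79153401 to 79153700, was higher with pR-Ea, at 7.42 (SE 1.06) and 4.72 (SE 1.06), from 4 SCP1 reads. Between pR-Ea and pPGK, chromosome 19, 4988951 to 4989300, was higher with pR-Ea at 6.47 (SE 0.73) and 5.41 (SE 0.76), from 6 pPGK reads. Chromosome 18, 82730201 to 82730450, was at 5.22 (SE 0.87) and 3.28 (SE 0.88), also from 6 pPGK reads. It was below input with both promoters, at -1.67 with pR-Ea and -4.96 with pPGK. Chromosome 17, 56381401 to 56381750, was at 4.87 (SE 0.71) and 4.18 (SE 0.49), from 20 pPGK reads. Chromosome 15, 57828701 to 57829150, was lower with pR-Ea at -5.81 (SE 0.57), and -1.20 (SE 0.22) after division.

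Comparisons that used the same library shared calls. Regions changed the same way in pPGK and in pR-Ea, each against SCP1, numbered 3567, of which 2637 were higher and 930 lower. Independent lists would share 1072 and 292, and simulated unchanged regions with the shared library 197 in all. Those changed the same way in pR-Ea against pPGK and in pPGK PMA_I against pPGK numbered 43, of which 38 were higher and 5 lower, against 9.36 and 1.86 for independent lists and 6.03 simulated. Splitting the shared library's reads between the 2 comparisons gave 3521 and 40. Each shared library is 1 library, and a split of its reads does not separate its plasmids, so part of the excess may come from the shared library. These calls are on reporter reads alone, which follow the plasmid inputs as given above, and neither expected number allows for differences between inputs.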

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

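The tests of removed positions, of selection on low pPGK counts, of the filter, of input abundance and of position splits, and the lists high with pPGK or with SCP1 were chosen after related results had been seen. With 1 library per group, none of the differences in this part was tested against replicates. The intervals in this part come from regions or reads within these single libraries. They do not cover variation between cultures, and regions are not independent replicates.

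Some regions were above input with 1 promoter and below input with another, and this difference was not tested. There were 2 regions high with SCP1 and low with pPGK, 8 high with SCP1 and low with pR-Ea, 2 high with pPGK and low with SCP1, 8 high with pPGK and low with pR-Ea, 3 high with pR-Ea and low with SCP1, and 2 high with pR-Ea and low with pPGK. Each number was below that of independent lists, such as 44.3 for the first. Chromosome 4, 155153351 to 155153750, had a log2 ratio of 1.27 (SE 0.24) with SCP1, -2.07 (SE 0.28) with pPGK and -2.55 (SE 0.19) with pR-Ea.

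Positions that no comparison used held a larger share of reporter than of input reads in a few cases. Of reads at used positions, 52.7% of the pPGK reporter lay outside regions against 46.4% of its input, and 57.2% of the pPGK PMA_I reporter. The shares went the other way with SCP1 (40.4% against 43.2%) and pR-Ea (48.0% against 48.3%). A stretch of 10 kb on chromosome 2, singled out for its counts, held 0.118% of SCP1 reporter reads against 0.103% of input. It was below input with pPGK (3.83% against 4.29%), pPGK PMA_I (0.515% against 4.29%) and pR-Ea (0.519% against 0.567%). Chromosome Y held 0.00836% of pR-Ea reporter reads against 0.00787% of input, with a counting interval of the log2 ratio from 0.000285 to 0.17. Such intervals are too narrow, so chromosome Y is not shown to lie above input there. It was below input in pPGK PMA_I (0.00710% against 0.0196%), and the interval included 0 with SCP1 and pPGK. These shares are of all placed reads, and in pPGK PMA_I excluded, low mapping quality positions held 9.90% of reporter reads against 43.9% of input, so its low values go with a reporter count filtered differently from its input and cannot be read as activity.

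In the first pattern weighed, 564 regions were below input with all 3 promoters. A single position with very many reads would not leave 94.3% of them (95% interval 92.1 to 96.1) at or below 50% of input with each promoter once the position with most reads was removed. Several such input positions are not excluded, since only 1 position per region was removed in each library. Sequence acting in 1 orientation only, such as an RNA processing signal in the transcript, cannot be told apart: 69.2% (63.5 to 74.4, of 295 with enough reads) were low on both strands of the pPGK library, past the bound of 50% written beforehand, but no label or value shows that read strand is insert orientation. Choosing low regions would force this in only 19.0%, and it held in 57.6% of 429 regions chosen without pPGK, against 5.80% of those not low with all 3 promoters, so the doubt is the meaning of strand. Repeated sequence remains open as a technical explanation, since the median share of excluded pPGK reads was higher by 12.9 percentage points (11.2 to 14.7), past the bound of 10 set before the value was seen. Shared calls rose from 0.995% of regions with at most 2% of reads excluded to 9.04% of those with 25 to 50%; whether this reflects read placement or an effect of the repeats themselves, which the series title names, was not tested, since no mm9 sequence was used here.

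Activity of the pPGK library differed between strands of the same region, with a Spearman rho of 0.18 over 14452 regions. Few positions per strand do not account for it, because sets of positions split without regard to strand had a rho higher by 0.55. Uneven input does not either: the rho was higher by 0.0310 in regions with even input. Placement by an assumed fragment length would make long regions more alike between strands, and they were less alike, by -0.20. An effect of insert orientation is a hypothesis that these files could not test, because SCP1 (rho 0.88) and pR-Ea (0.91) appear to be read from both ends, and no biological explanation was tested.

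The regions that rose with PMA and ionomycin started low. Selection on low pPGK counts is argued against by the 733 regions low with SCP1 and pR-Ea, which share no reads with the change and had a median change 0.32 above that of all regions (0.29 to 0.36). The excess was 0.33 (0.30 to 0.37) against lists matched on input abundance and 0.26 (0.15 to 0.33) where at most 2% of pPGK reads were excluded. Neither abundance nor the differing filter was therefore the whole cause of this excess. Across all regions, however, the change had a rho of -0.39 with SCP1 input reads and -0.32 with pR-Ea input reads. With activity the rho was weaker, at -0.18 for SCP1 and -0.10 for pR-Ea. Regions called higher made up 0.336% of those with at most 2% of pPGK reads excluded and 0.475% at 2 to 10%. The share was 1.05% at 10 to 25% and 0.691% at 25 to 50%. A single position carrying the rise is argued against only narrowly, as 63.3% of the 90 regions (52.5 to 73.2) kept a log2 change of 1 without the position with most reads. That position was chosen in each library by itself, and the argument is weaker where the 2 differ. Several positions are not excluded, since the plus strand kept 32 of the 90 and the minus strand 60. Counting distinct positions kept 1, which cannot decide this because positions hardly follow reads per position. An interval over positions kept 87. Regions above input rose from 586 to 1235, yet a ratio compressed over the whole range cannot be told apart, because only 9 regions were high with SCP1 and pR-Ea (difference -0.00778, interval -0.37 to 0.65), and those high with pPGK (0.05, 0.02 to 0.08) and 566 high with SCP1 (-0.05, -0.09 to -0.02) went opposite ways. The list high with pPGK was chosen on reads that enter the change, a choice that by itself would lower its change. The SCP1 list shares no reads with the change. The stimulus itself stays open as an untested explanation in 1 library.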

How the results depend on the processing

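Each strand alone, the 90% share, the mapping quality and double-listing settings, removal of the main position, the interval over positions, region thresholds of 2 and 5, and every alternative for activity were chosen after the data were seen. Division by input was named in the design beforehand but not among the listed alternatives. Of the counts under alternatives, 132 stayed within 1.5-fold of the main count and 27 did not. Of the values under alternatives of the leading 8 regions per side for pPGK PMA_I against pPGK and the leading 3 elsewhere, 518 kept their direction and call, 45 kept their direction and lost the call, and 7 turned. No value exists for a named region left with no reads by a setting.

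Counting distinct positions gave 660 (SCP1), 312 (pPGK), 241 (pPGK PMA_I) and 174 (pR-Ea) activity calls, and 11 (pPGK PMA_I against pPGK), 3974 (pPGK against SCP1), 1631 (pR-Ea against SCP1) and 2103 (pR-Ea against pPGK) changed regions. By construction this count can hardly follow reads per position. A 1.5-fold threshold, looser by construction, gave 6382, 5741, 6771 and 4580 activity calls in the same order, and 1053, 9866 and 9612 changed regions for pPGK PMA_I against pPGK and for pR-Ea against SCP1 and pPGK. The 90% share, which keeps 12770 regions, gave 1635, 1076, 1665 and 785 activity calls, and 57, 4452 and 3830 changed regions in the first 3 comparisons. Division by input gave 1435, 2193 and 1709 in the 3 promoter comparisons. Without the position with most reads, chosen in each library by itself, 63 of the 99 changed regions of pPGK PMA_I against pPGK kept their call. The plus strand alone gave 322 changed regions there, with 37 of the 99 kept, and the minus strand alone 290, with 64 kept. The causes were not tested except where the construction is given.

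In pPGK PMA_I against pPGK, chromosome 8, 12546851 to 12547150, turned to -0.050 on the plus strand; chromosome 9, 71530101 to 71530350, to 0.18 by distinct positions and 0.28 on the minus strand; chromosome 3, 9250601 to 9250850, to 1.08 on the plus strand; and chromosome 6, 121476551 to 121476800, to 0.45 by distinct positions and 0.32 on the minus strand. Chromosome 9, 22272551 to 22272950, turned to 0.0569 for pPGK against SCP1 after division by input, 1 of 3 that turned so among all 72 named regions of the promoter comparisons. Classes of tandem repeats, transcription factor sites, gene lists and fixed control regions were not run without an mm9 genome and annotation. No paired analysis was possible because each group held 1 library.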

Other observations

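All values in this part were computed after the main results were seen, and no explanation was tested for them.

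In the 564 regions chosen for low activity the ratio was lowest near the centre. With SCP1 the median log2 ratio was -2.20 within 100 bp of the centre (564 regions), -1.77 from 100 to 200 bp (542), -1.25 from 200 to 300 bp (376), -1.02 from 300 to 400 bp (206) and -1.23 from 400 to 450 bp (67). With pR-Ea the values were -1.79, -1.54, -1.20, -0.84 and -1.42. Longer distances hold fewer regions, so the values do not follow the same regions outwards. The regions were also chosen on the same reads, so the choice alone could give a ratio farthest from 0 near the centre. Regions high with SCP1 had 1.26, 1.21 and 0.86 at the first 3 distances. In all regions together the medians with SCP1 were between -0.15 and -0.11 over the first 3 distances, then -0.21 and -0.31.

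Neighbouring regions were weakly alike. Adjacent regions under 2000 bp apart had a Spearman rho of 0.18 with SCP1 (1203 pairs), 0.08 with pPGK, -0.00611 in pPGK PMA_I and 0.04 with pR-Ea. At 50000 to 500000 bp the values lay between -0.00258 and 0.0138, across regions, which are not independent replicates.

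The X chromosome stood apart in several values. Its 343 regions had a median log2 activity of 0.02 with SCP1, above all 10000 random lists of the same size matched on abundance (95% of them from -0.22 to -0.06), and 0.07 with pR-Ea, at percentile 99.8. With pPGK the median of 0.13 was at percentile 88.6 and in pPGK PMA_I the median of 0.08 at percentile 47.3. The median change in pPGK PMA_I against pPGK was -0.00523, at percentile 0.670 (95% of lists from 0.00547 to 0.0833). The X chromosome also had the largest share of regions above input of any chromosome with SCP1 (5.25%), pPGK (6.12%) and pPGK PMA_I (11.4%), though not with pR-Ea (0.583%). These are descriptions of single libraries.

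Activity differed at least 2-fold between strands in 27.3% of 14422 regions with pPGK and 18.1% in pPGK PMA_I. Both libraries are divided by the same input, whose strand balance also varied, so the 2 shares are not separate observations.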
